A study of Homo sapiens with 5 samples.

How the data were processed

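Total RNA of HL-60 cells infected with Anaplasma phagocytophilum and of mock-infected cells, both at 3 days after infection, was hybridised in pairs to 5 spotted 2-colour arrays. Per the labels, 5 µg of each RNA was labelled with a Genisphere Array900 kit and SuperScript II, infected RNA with a red Alexa Fluor dye (channel 1) and mock RNA with a green one (channel 2). Slides were scanned with a ScanArray Express and images read with GenePix Pro 4.0, per the labels, and normalized log ratios were obtained in R and Bioconductor through a web tool for GenePix output. The normalization method, background correction and spot filters are not given in the sources used here. The labels call the arrays biological replicates, so the p-values measure the spread between these 5 pairs of cultures.

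The deposited values are log ratios, taken here as log2 because the highest value, 13.35, lies above what natural or base-10 logs of 16-bit intensities could reach. Neither the base nor the direction is stated, and infected over mock was used as the likely direction. Medians of arrays 1 to 5 were −0.02, −0.05, −0.03, −0.04 and −0.01, and SDs 0.88, 0.76, 0.97, 0.76 and 0.90. Missing values numbered 264, 1634, 2570, 389 and 226 of 23232. At most 0.0351% of values were identical between arrays, so no array was a copy of another. No intensities were used, so signal over background is unknown.

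Gene symbols came from the platform annotation: 17744 rows had 1 symbol, 164 had several and 5324 had none, and no gene is named from the last 2 kinds. Of the annotated rows 17655 matched a current Entrez record, and 0 symbols changed. No genome build is named for the array, so no coordinates are given. Control spots were not marked in the values, so the layout was read from accessions alone, without the ratios: 48 subgrids of 484 rows, with 8 positions per subgrid holding runs of 4 spots of 1 accession (384 rows, controls) and 8 positions never named (384 rows, blanks or landmarks). These were left out. Another 16 positions carried probes printed in duplicate, 768 pairs, and all 657 named pairs held the same accession; these were averaged. That left 21696 probes.

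An intercept was fitted per probe with lmFit and tested against 0 (two-sided) with eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0) for the 21611 probes measured on at least 3 arrays, 18147 of them on all 5. Calls were made at a Benjamini-Hochberg adjusted p of 0.05, with a mean log2 ratio of 1 in size as the additional 2-fold criterion. For 29 gene lists with at least 5 measured genes, probes with exactly 1 symbol were averaged per gene and array, the fit was repeated over 14917 genes, of which 1738 had several probes, and the moderated statistics were tested with cameraPR at a preset correlation of 0.01. Because the adjustment covers fewer rows, a gene near the threshold can pass in one fit and not in the other. Estimated-correlation camera and fry used the 12988 genes measured on all 5 arrays. A count adjusted over the list alone applies the Benjamini-Hochberg method to the list's members only.

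The tests of the report, its 29 lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined. The comparison of called probes with other probes of their genes, those 2 alternatives and the further lists and tests of the closing section were chosen after the main results were known. The rule took, per direction, the 12 genes of largest mean ratio among called probes with the same sign on every array, at least 4 arrays and exactly 1 symbol, then up to 4 members of smallest p from each list, and 13 genes from the literature on this infection, of which 10 were measured under a name. Genes outside this rule are PGK1, SLC2A1, GAPDH, LDHA, PDK1, MSMO1, TUBA1B and ZNF395 in the report and members of the later lists in the closing section, chosen after their values were seen. The steps were tested on simulated data with the spread of the 21611 probes and 200 changed probes in each of 5 sets. Of changes of log2 size 1, 15.2% were recovered, with 62.7% of size 2 and 86.1% of size 3. Changes below 2-fold were therefore mostly out of reach of the probe-level test. Of the calls 1.09% were false, and a single set without changes gave 0 calls. The simulated noise had random signs, independent between probes and arrays. The false share thus leaves out correlation between probes and any bias of a probe that repeats across arrays, such as a dye preference. Alternatives were centring or scaling of arrays, other limits on missing spots, a robust prior or no variance moderation, array weights, other thresholds, spots kept apart, other list tests, the median probe per gene, and leaving out each array.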

Results

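HL-60 is an established human promyelocytic leukaemia line whose cells resemble immature neutrophils, and Anaplasma phagocytophilum is a bacterium that lives and multiplies inside cells of that lineage. RNA of infected cultures was compared with RNA of mock-infected cultures at 3 days after infection on 5 spotted 2-colour arrays, 1 for each of 5 biological replicates named in the labels. On every array the infected RNA carried a red and the mock RNA a green Alexa Fluor dye, with 5 µg of total RNA per channel, so the dyes were never exchanged between the conditions. Each value was therefore already a ratio of infected to mock culture within a replicate, and the question was which transcripts differed between them. The table held 23232 rows, of which arrays 1 to 5 measured 22968, 21598, 20662, 22843 and 23006. Spot intensities and background were not used here, so the brightness behind a ratio is unknown, and the number of arrays limits the precision. Below, values are mean log2 ratios ± SD with n = 5 arrays unless another n is given.

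Among called probes with a single gene symbol and at least 4 arrays, the largest positive ratios belonged to LILRA5, a leukocyte immunoglobulin-like receptor (6.68 ± 1.35, 102-fold), PLS3, an actin-bundling plastin (5.28 ± 0.48, n = 4), and CAMTA1, a calmodulin-binding transcription factor (5.28 ± 1.07). Among the same probes the largest negative ratios belonged to AGFG2, a protein with an ARF GTPase-activating domain (−6.55 ± 2.66, 93.9-fold), APBB2, an adaptor that binds the amyloid precursor protein (−4.65 ± 1.61), and the transcription factor DMRTA2 (−4.53 ± 1.57). As groups, genes of glycolysis and of cholesterol synthesis and uptake had negative ratios, with medians of −0.31 and −0.26 (adjusted p = 0.00208 for both, and adjusted p = 0.447 and 0.338 with an estimated correlation). A positive ratio is read here as higher in infected cells. That direction is likely, from the labels' order of channels and the usual red-over-green form of such ratios, but neither it nor the log base is stated. If the values were deposited as mock over infected, every sign below turns.

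Among 21611 probes tested with limma, 171 passed a Benjamini-Hochberg adjusted p of 0.05, 109 higher and 62 lower in infected cells, which is 0.791% of the probes. All 171 had the same sign on every array that measured them. A mean change of at least 2-fold was met by 167 of them, 107 higher and 60 lower. The median size of a called ratio was 2.31 and the smallest 0.91, against a median size of 0.22 over all probes. Of the called probes, 124 had a single gene symbol (74 higher, 50 lower) and 47 had none or several. At an unadjusted p of 0.05, 2808 probes passed, 1216 higher and 1592 lower, where 1080.55 are expected by chance. The count rested on the pooled spread and on all 5 arrays: 0 probes passed without limma's variance moderation (2659 at unadjusted p), and 12, 18, 34, 48 and 98 passed without replicate 2, 1, 5, 3 and 4, respectively.

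Further genes that rose by this test were HS3ST2, a heparan sulfate sulfotransferase (5.27 ± 1.41, n = 4), MOCOS, the molybdenum cofactor sulfurase (5.24 ± 1.61), RAP1GAP2, a GTPase-activating protein of Rap1 (5.07 ± 1.07), and COPZ2, a coatomer subunit (4.73 ± 0.50, n = 4). They were followed by the teneurin TENM1 (4.38 ± 1.25), FRMD4A (4.33 ± 0.97, n = 4), the kallikrein protease KLK11 (4.22 ± 1.19), the ribonuclease angiogenin, ANG (4.10 ± 1.12), and the melanocyte enzyme TYRP1 (3.96 ± 1.43). Adjusted p-values of the 12 highest ran from 0.00871 for LILRA5, PLS3 and COPZ2 to 0.036 for TYRP1.

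Genes that fell included DACT3, a modulator of Wnt signalling (−4.48 ± 0.61, n = 4), the nuclear import receptor TNPO1 (−3.89 ± 1.49), the potassium channel KCNK3 (−3.80 ± 1.38), the ferroxidase HEPH (−3.78 ± 1.34) and C9orf72 (−3.66 ± 1.49). ELAVL1, an RNA-binding protein that stabilises transcripts with AU-rich elements, stood at −3.41 ± 0.55 and had the smallest adjusted p of the 12 lowest, 0.00871. GZMA, a protease of cytotoxic lymphocytes, stood at −3.21 ± 1.31, the immediate-early transcription factor EGR3 at −3.17 ± 1.03 and the zinc finger gene ZNF449 at −3.12 ± 0.64. GZMA was the closest of these to the threshold, with an adjusted p of 0.0489 among probes and 0.0502 when probes were first averaged per gene.

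**Figure D1:**
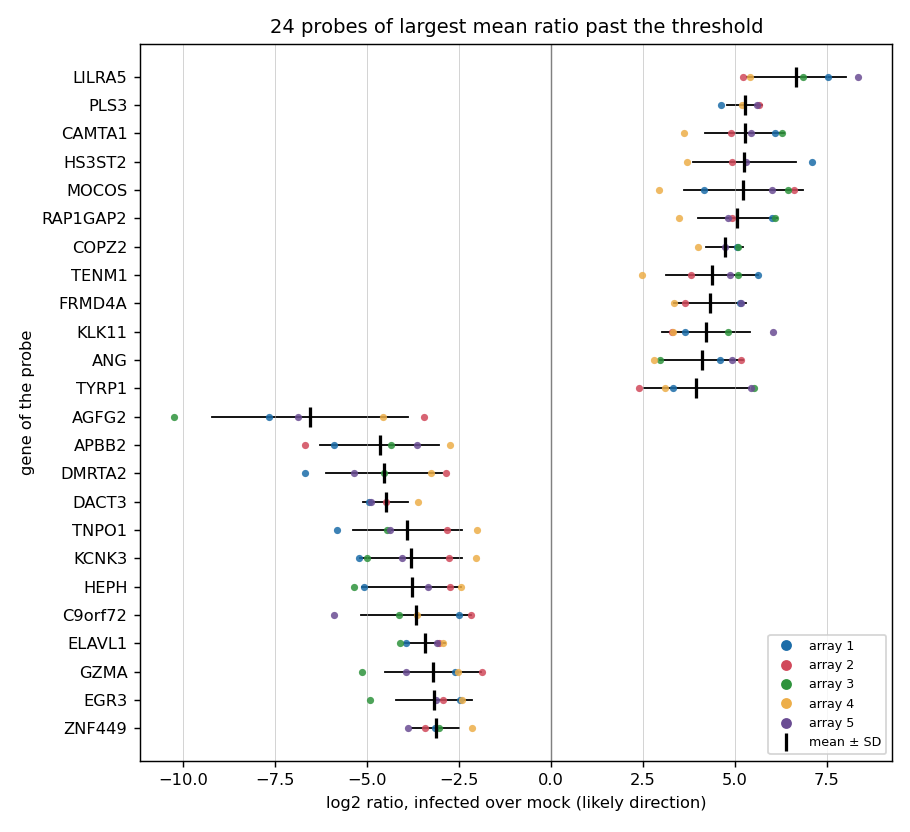
Log2 ratio of infected over mock (horizontal, likely direction) for the 12 probes of largest positive and the 12 of largest negative mean among those past the adjusted p of 0.05 with a single gene symbol and at least 4 arrays, named by gene; points are arrays, vertical ticks are means and lines are ± SD. Every point of a probe lies on the same side of 0, which was a condition for being shown. The means run from 6.68 for LILRA5 to −6.55 for AGFG2.

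For 6 of these 24 genes the array held further probes, and none of those passed the threshold. The other AGFG2 probes stood at 0.59 ± 0.42 and 0.09 ± 0.27, the other TENM1 probes at −0.11 ± 1.2 and −0.20 ± 0.64, and the other FRMD4A probe at 0.08 ± 0.24. The second probes of TNPO1, C9orf72 and ELAVL1 stood at −0.23 ± 0.60, −0.14 ± 0.54 and −0.31 ± 0.41. Over the called probes with another probe for the same gene from a different accession, 35 called probes were set against 43 others: the others, turned to the sign of the called probe and averaged for each called probe, had a median ratio of 0.050 over the 35, against a median size of 2.45 for the called ones. In limma 0 of the 43 passed in either direction, and 3 in the called direction and 3 in the opposite one had an unadjusted p under 0.05. The other probe shared the accession for 1 further called gene, ZNF395, where the called probe stood at −0.91 ± 0.06 and the other at −1.59 ± 0.64 (adjusted p = 0.0575). With it included the median was 0.056. The named changes above are therefore measurements of single probes.

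**Figure D2:**
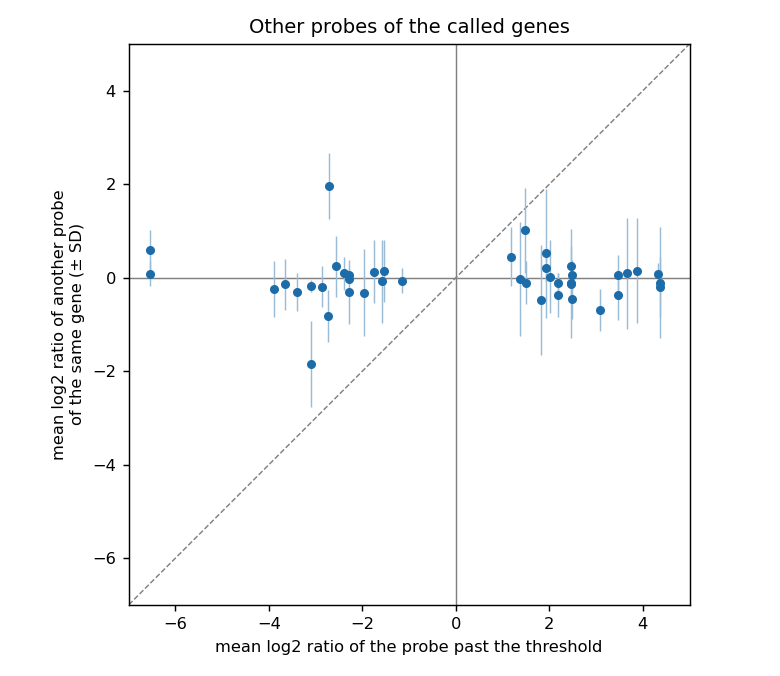
Mean log2 ratio of each probe past the threshold (horizontal) against the mean log2 ratio ± SD of another probe of the same gene from a different accession (vertical), for 43 pairs; the dashed line marks equal ratios. Most points lie near 0 on the vertical axis, and AGFG2 at −6.55 is set against 0.59 and 0.09.

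For gene groups, probes were averaged per gene, which gave 14917 genes, of which 94 passed, 58 higher and 36 lower. The 29 gene lists held 821 of these genes. In limma 0 of the 821 passed when adjusted over all genes, and 124 had an unadjusted p under 0.05, 39 with positive and 85 with negative ratios, where 41.05 are expected. Adjusted over the list alone, 22 memberships passed in 11 lists. Of the lists as groups, 3 passed cameraPR with a preset correlation, all towards lower: glycolysis, cholesterol synthesis and uptake, and ribosomal proteins. With an estimated correlation between genes 0 of the 29 passed (2 at an unadjusted p under 0.05), and the self-contained fry test called 6, also all lower.

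The glycolysis list, which also holds glucose transporters and hypoxia-induced genes, shifted lower: 16 of 23 measured members had negative ratios and the median was −0.31, negative on 5 of 5 arrays (adjusted p = 0.00208, and adjusted p = 0.447 with an estimated correlation). Adjusted over the list alone, 5 members fell: the glucose transporter SLC2A3 (−0.90 ± 0.25), the aldolase ALDOC (−0.75 ± 0.30), the enolase ENO2 (−1.06 ± 0.54), PFKFB3, which makes the activator of phosphofructokinase (−1.15 ± 0.61), and the phosphoglycerate kinase PGK1 (−0.55 ± 0.17). Over all genes their adjusted p-values were 0.0584, 0.102, 0.103, 0.109 and 0.143. The main glucose transporter of many cell lines, SLC2A1, had a ratio of 0.28 ± 0.12, and GAPDH one of 0.01 ± 0.09.

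The cholesterol list also shifted lower, with 19 of 23 members negative and a median of −0.26, negative on 5 of 5 arrays (adjusted p = 0.00208, and adjusted p = 0.338 with an estimated correlation). Without replicate 4 the adjusted p was 0.0674. Adjusted over the list alone, 3 members fell: HSD17B7 (−0.76 ± 0.22), the isopentenyl diphosphate isomerase IDI1 (−0.63 ± 0.15) and DHCR7, which catalyses the last step to cholesterol (−0.59 ± 0.20). INSIG1, an inhibitor of sterol-regulated transcription that is itself induced when sterols are low, had a ratio of −0.72 ± 0.47 and did not pass (adjusted p = 0.0542 over the list alone).

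**Figure D3:**
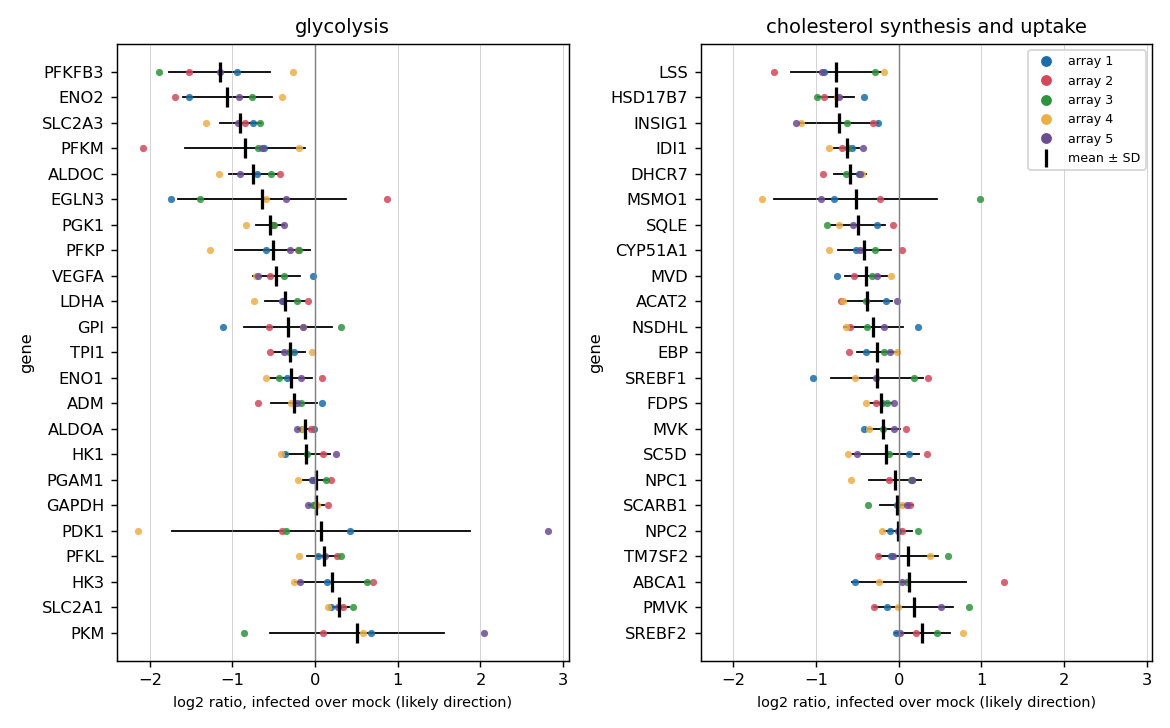
Log2 ratio of infected over mock (horizontal, likely direction) for the measured genes of the glycolysis list (left) and of the cholesterol list (right), sorted by mean; points are arrays, vertical ticks are means and lines are ± SD. Negative means make up 16 of 23 genes on the left and 19 of 23 on the right, while single genes such as PDK1 and MSMO1 spread across 0.

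Among genes of protein synthesis, ribosomal proteins shifted lower by a small amount: 50 of 55 had negative ratios, with a median of −0.13 (adjusted p = 0.0456, and adjusted p = 0.338 with an estimated correlation). The call ended when each array was centred on its median (adjusted p = 0.0626), when a gene's median probe replaced the mean of its probes (0.101), and without replicate 1, 2, 4 or 5 (0.155, 0.116, 0.144 and 0.0692). In limma 0 of its members passed over the list alone, and 6, all negative, had an unadjusted p under 0.05. The smallest p-values belonged to RPS27L (−0.80 ± 0.36), RPL28 (−0.51 ± 0.36), RPL10 (−0.62 ± 0.56) and RPS3 (−0.55 ± 0.49). Of 16 aminoacyl-tRNA synthetases 11 were negative (median −0.07, cameraPR adjusted p = 0.366, and adjusted p = 0.673 with an estimated correlation). This list passed fry towards lower (adjusted p = 0.0288). HARS1 fell when adjusted over the list alone, although its 2 probes stood at −2.17 ± 0.98 and 0.17 ± 0.22. IARS1 (−0.76 ± 0.45), LARS1 (−0.36 ± 0.22) and SARS1 (−0.54 ± 0.74) did not pass.

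**Figure D4:**
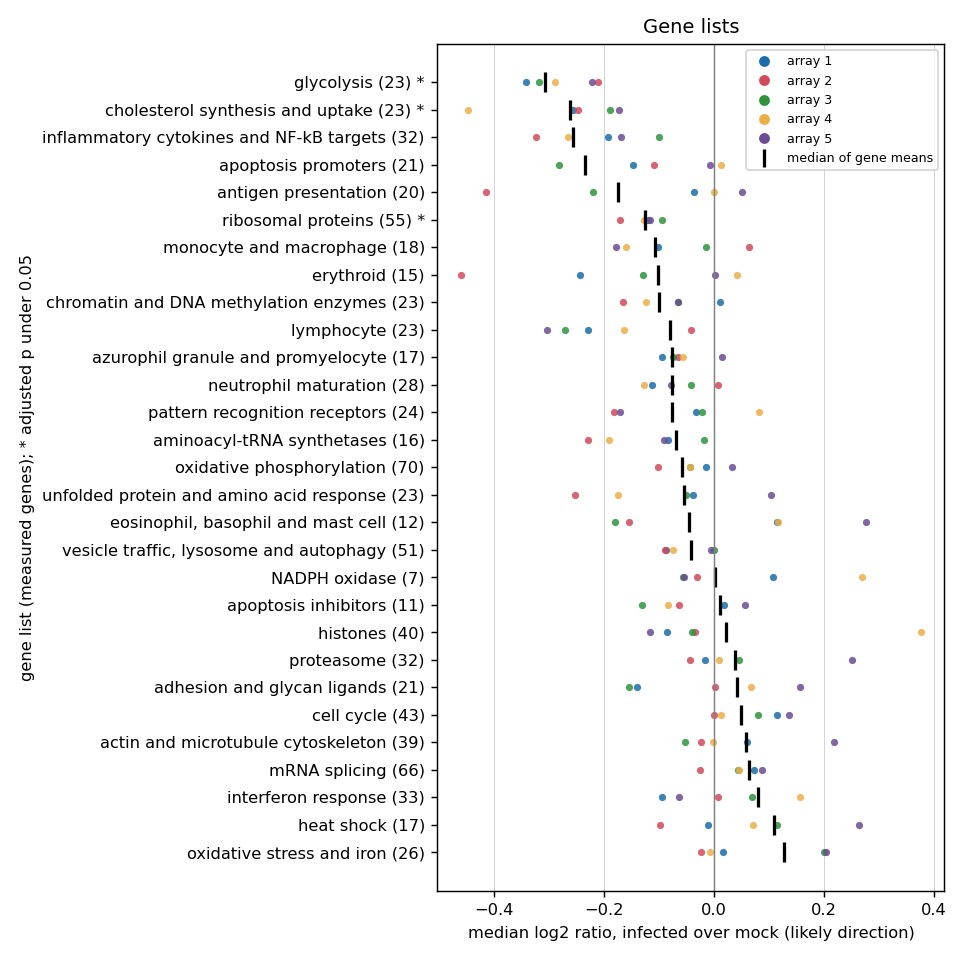
Median log2 ratio of infected over mock (horizontal, likely direction) of each of the 29 gene lists, with the number of measured genes in brackets; points are the medians on single arrays, vertical ticks the median of the gene means, and asterisks mark cameraPR adjusted p under 0.05. The glycolysis and cholesterol lists lie lowest, at −0.31 and −0.26, followed by the inflammatory list, also at −0.26. All 5 arrays lie below 0 for these lists, as they do for the ribosomal, aminoacyl-tRNA synthetase, lymphocyte and vesicle lists.

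Of 32 inflammatory cytokine and NF-kB target genes 21 were negative, with a median of −0.26. The list did not pass cameraPR (adjusted p = 0.178, and adjusted p = 0.447 with an estimated correlation) but passed fry (adjusted p = 0.0236). Adjusted over the list alone, 2 members fell, the neutrophil chemokine CXCL8 (−0.81 ± 0.20) and the interferon-induced chemokine CXCL10 (−1.15 ± 0.51), with adjusted p-values over all genes of 0.0605 and 0.0779. The cytokine TNF (−0.47 ± 0.13) and the NF-kB inhibitor NFKBIE (0.53 ± 0.22) did not pass. The interferon list (33 genes, median 0.08, adjusted p = 0.559) had members on both sides, none past the threshold: RSAD2 at −1.26 ± 0.68, IFITM2 at 1.42 ± 0.94, MX1 at 0.93 ± 0.53 (n = 4) and IFI6 at 0.54 ± 0.28.

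Pattern recognition receptors and their adaptors (24 genes) had a median of −0.08 and did not pass (adjusted p = 0.766). The members of smallest p were the inflammasome sensor NLRP3 (−0.92 ± 0.51, n = 3), LY96 (0.38 ± 0.35), the caspase CASP1 (0.37 ± 0.34) and SIGIRR (−0.36 ± 0.38). Antigen presentation genes had a median of −0.18, with 15 of 20 negative, and did not pass either (adjusted p = 0.43). Their examples were HLA-DQB1 (−0.81 ± 0.39, n = 4), HLA-DMB (−0.46 ± 0.31), the peptide transporter TAP2 (0.42 ± 0.13, n = 4) and TAPBP (−0.44 ± 0.51).

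Markers of the myeloid lineage itself moved little as groups, and none of their lists passed cameraPR. The azurophil granule and promyelocyte list (17 genes) had a median of −0.08 (adjusted p = 0.559), with the defensin DEFA4 at −0.75 ± 0.34, BPI at −0.51 ± 0.39, the elastase ELANE at 0.27 ± 0.20 and RNASE2 at 0.26 ± 0.19, none past the threshold. In the neutrophil maturation list (28 genes, median −0.08, adjusted p = 0.581) the granulocyte adhesion molecules CEACAM8 (−0.92 ± 0.42) and CEACAM6 (−0.77 ± 0.35) fell when adjusted over the list alone. The water and glycerol channel AQP9 (−0.62 ± 0.38) and the chemokine receptor CXCR2 (1.81 ± 1.52) did not pass. The monocyte and macrophage list (18 genes, median −0.11) had an adjusted p of 0.559 in cameraPR and of 0.673 with an estimated correlation. It passed fry towards lower (adjusted p = 0.0288). In that list SPP1, which encodes osteopontin, fell over the list alone (−1.10 ± 0.36). MRC1 (0.65 ± 0.22, n = 4), LGALS3 (1.38 ± 1.22) and FCN1 (−0.65 ± 0.54) did not pass.

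Markers of other blood cells showed no shift of a whole list. In the lymphocyte list (23 genes, median −0.08, adjusted p = 0.48) the granzymes moved apart: over the list alone GZMA (−3.21 ± 1.31) and the cytokine receptor chain IL2RB (−0.97 ± 0.26, n = 4) fell and GZMB (0.84 ± 0.24) rose. CD8A, at −0.65 ± 0.47, did not pass. In the erythroid list (15 genes, median −0.10, adjusted p = 0.766) the globin HBB fell (−0.83 ± 0.48) and the transcription factor TAL1 rose (0.99 ± 0.63) over the list alone, while HBA1 (1.11 ± 1.12) and GATA1 (−0.45 ± 0.63) did not pass. No member of the eosinophil, basophil and mast cell list passed (12 genes, adjusted p = 0.559), with PRG3 at 1.01 ± 0.67, SIGLEC8 at 0.55 ± 0.44, FCER1A at −0.87 ± 0.83 and ENPP3 at 0.62 ± 0.64. The median of that list was −0.05 and its mean 0.22, with the test pointing to higher. Median and mean also differed in sign for the monocyte list (mean 0.08) and the neutrophil list (mean 0.01), where the test pointed to lower.

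Cell death genes did not pass as groups. Apoptosis promoters had a median of −0.24, with 14 of 21 negative (adjusted p = 0.43), including BNIP3L (−0.62 ± 0.20), BAD (0.87 ± 0.66), CASP6 (−1.09 ± 1.06) and BNIP3 (−0.86 ± 0.91). Apoptosis inhibitors (11 genes) had a median of 0.01 and a mean of −0.10, and the test pointed to lower (adjusted p = 0.559). Among them were BCL2A1 (−0.61 ± 0.36), XIAP (−0.40 ± 0.31), BCL2 (−0.29 ± 0.31) and BCL2L2 (−0.34 ± 0.45), none past the threshold.

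In the heat shock list (17 genes, median 0.11, adjusted p = 0.366) the chaperone HSPH1 rose when adjusted over the list alone (0.83 ± 0.20), and HSPA9 (−0.46 ± 0.26), CRYAB (−0.36 ± 0.24) and HSP90AA1 (0.32 ± 0.20) did not pass. The probes of HSPA9 stood at −0.84 ± 0.40 and −0.07 ± 0.16. The list of the unfolded protein and amino acid response (23 genes) had a median of −0.06 (adjusted p = 0.517), with the stress transcription factor DDIT3 at −0.81 ± 0.36, XBP1 at −0.71 ± 0.62, DNAJC3 at −0.35 ± 0.13 and HSPA5 at 0.25 ± 0.13. The oxidative stress and iron list had a median of 0.13, with 19 of 26 members positive (adjusted p = 0.244). Its members of smallest p were GCLM, a subunit of the enzyme that starts glutathione synthesis (0.51 ± 0.17), the ferritin light chain FTL (−0.91 ± 0.91), SLC11A1 (0.42 ± 0.32, n = 4) and HMOX1 (0.43 ± 0.49). FTH1 was not measured under a gene name here.

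Genes that serve the uptake and housing of bacteria were also examined as lists. The vesicle, lysosome and autophagy list (51 genes) had a median of −0.04 (adjusted p = 0.563), and the lysosomal protease CTSL fell over the list alone (−1.10 ± 0.39), while VAMP3 (−0.48 ± 0.23), ATG7 (−0.44 ± 0.34) and ATP6V0D1 (0.42 ± 0.32) did not pass. The cytoskeleton list (39 genes) had a median of 0.06 (adjusted p = 0.517), with ARPC5 at 0.41 ± 0.18, EZR at 0.41 ± 0.28, CAPZB at −0.54 ± 0.55 and WASF2 at 0.83 ± 0.89, whose 2 probes stood at −0.32 ± 0.34 and 1.98 ± 1.76. The adhesion and glycan ligand list (21 genes) had a median of 0.04 (adjusted p = 0.68), with CD44 at −0.56 ± 0.33, ICAM1 at −0.43 ± 0.27, CEACAM1 at 0.77 ± 0.84 and CD47 at 0.32 ± 0.20. The 7 measured genes of the NADPH oxidase, which makes superoxide, had a median of 0.00 (adjusted p = 0.766). Those of smallest p were CYBB (0.21 ± 0.26), RAC2 (0.14 ± 0.13), RAP1A (−0.18 ± 0.42) and CYBA (−0.11 ± 0.12). The probes of CYBA stood at −0.31 ± 0.29 and 0.09 ± 0.25.

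Proliferation and nuclear lists stayed near 0. The cell cycle list (43 genes, median 0.05, adjusted p = 0.517) included AURKB (−0.51 ± 0.21), MYBL2 (0.41 ± 0.19), BUB1 (0.36 ± 0.23) and MCM3 (−0.66 ± 0.69), none past the threshold. Of 40 histone genes (median 0.02, adjusted p = 0.43), H2AC18 rose over the list alone (2.02 ± 0.87), and H2AX (0.66 ± 0.24), H1-2 (0.53 ± 0.20) and H1-4 (0.80 ± 0.50, n = 4) did not pass. The chromatin enzyme list (23 genes, median −0.10, adjusted p = 0.559) held EP300 (−0.63 ± 0.30), SMARCA2 (−0.65 ± 0.37), HDAC1 (1.03 ± 0.87) and HDAC6 (−0.49 ± 0.40). The splicing list (66 genes, median 0.06 with a mean of −0.0040 and a test pointing to higher, adjusted p = 0.559) held HNRNPF (−1.11 ± 0.97), PRPF8 (−0.56 ± 0.55), HNRNPU (0.30 ± 0.18) and HNRNPL (−0.48 ± 0.52).

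The proteasome list (32 genes) had a median of 0.04 (adjusted p = 0.517), with PSMC4 at 0.54 ± 0.22, PSMA4 at 0.23 ± 0.19, PSMD1 at −0.36 ± 0.57 and PSMD6 at 0.59 ± 0.16. The 3 probes of PSMD6 stood at 0.09 ± 0.34, 1.46 ± 0.66 and 0.22 ± 0.55. The oxidative phosphorylation list (70 genes) had a median of −0.06 (adjusted p = 0.559), with NDUFC2 at −2.18 ± 1.29, SDHA at 0.52 ± 0.18, ATP5MK at −0.51 ± 0.21 and NDUFA6 at −0.40 ± 0.16, none past the threshold.

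Genes that earlier work on this bacterium in HL-60 cells or neutrophils has dealt with were named whatever their result, and none passed over all genes. Besides those given above, NCF1, a cytosolic subunit of the NADPH oxidase, had a ratio of 0.00 ± 0.30, SELPLG, which encodes the selectin ligand the bacterium binds, 0.18 ± 0.22, and the fucosyltransferase FUT7 0.24 ± 0.26. The granule enzyme MPO stood at 0.02 ± 0.15 and the receptor TLR2 at −0.16 ± 0.59. For these 5 genes the SD between arrays exceeded the mean, and their 95% intervals in limma all included 0. HDAC1 had a positive mean but a ratio of −0.24 on array 2.

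The arrays shared a direction only in part. Across probes, which are not independent replicates, Pearson correlations between pairs of arrays ran from 0.171 to 0.36 with a median of 0.278 over 10 pairs, and Spearman correlations from 0.0765 to 0.289 with a median of 0.18. Array 4 had the lowest mean Pearson correlation with the others, 0.196. Among probes measured on all 5 arrays, 16.1% had the same sign on all of them, where chance gives 6.25%. A dye preference of a probe would also repeat its sign, so the excess cannot be credited to infection alone. Repeated spots of the 11 named control genes, 16 spots each, had means from −0.32 ± 0.26 for LDHA to 0.13 ± 0.10 for TUBA1B. LDHA is a member of the glycolysis list. GAPDH stood at −0.01 ± 0.10. Control spots of the ribosomal protein genes RPL5 and RPS9 differed in sign, at −0.17 ± 0.26 and 0.10 ± 0.18.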

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

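The comparison of called probes with other probes of their genes and the reading of the CXCL8 sign were chosen after the values had been seen; the other explanations in this part were written down after the called probes were known but before the result of each test was seen. Of 178 values examined for a single array far from the other 4, 11 met a Dixon test at the 5% level, where chance gives about 1 in 20.

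For EGR3, array 3 stood at −4.92 and the others between −3.12 and −2.40. For NCF1, array 4 stood at 0.52 and the others between −0.25 and −0.06. For the ribosomal gene RPL10, array 2 stood at −1.60 and the others between −0.58 and −0.23. For the actin regulator WASF2, array 1 stood at 2.37 and the others between 0.24 and 0.81. For PRG3, array 5 stood at −0.14 and the others between 1.00 and 1.43, and for FCER1A array 3 stood at −2.29 and the others between −0.82 and −0.27. For EP300, array 2 stood at −0.11 and the others between −0.87 and −0.69. For ELANE, array 4 stood at 0.61 and the others between 0.13 and 0.27. The median of the histone list was 0.38 on array 4 and between −0.12 and −0.04 on the others. Array 4 also had a mean correlation with the other arrays of 0.196, against 0.26 to 0.286.

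Outside the tested probes, 3 runs of 4 unnamed control spots had strongly negative ratios, with medians over the arrays of −7.76 in subgrid 35, −7.52 in subgrid 39 and −7.58 in subgrid 40, and a run in subgrid 36 had a median of −3.66. The other unnamed run of each of these subgrids lay near 0, at −0.086, −0.205, −0.095 and −0.042 in subgrids 35, 39, 40 and 36. In all 14 such spots had means below −4, while the 11 named control genes had means between −0.32 and 0.13.

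CXCL8 stood at −0.47 on array 2 and between −0.99 and −0.84 on the others, with a mean of −0.81 ± 0.20. Infected HL-60 cells have been reported to secrete more of this chemokine, so a negative ratio may mean that the values were deposited as mock over infected. Transcript and secreted protein at a single time need not go together, and no value here states the direction, so these readings cannot be told apart. A turned sign would turn every direction given in the report, the glycolysis and cholesterol lists included.

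The 171 called probes form the first pattern weighed. With the signs of the arrays turned in every possible way, 1 of 16 patterns, the real one, gave as many; the highest other gave 1 probe, and 16 patterns are too few for a share under 0.05. A dye preference of single probes would give the same sign on all arrays and cannot be told apart from infection, because 0 arrays carried the dyes the other way round. A signal of the single probe sequence, such as cross-hybridisation or a particular splice form, may account for many calls: for 35 called probes the other probes of the same gene from a different accession, turned to the called sign and averaged for each called probe, had a median of 0.050 (95% bootstrap interval −0.12 to 0.15) against 2.45, and 19 of 35 shared the sign, with ZNF395, whose other probe shares its accession and its sign, left out (0.056 and 20 of 36 with it). Across 1490 genes with 2 probes, means also correlated weakly (Pearson 0.0458, Spearman 0.0771), and a response to infection, the difference the design names, stays open for each probe.

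The second pattern is large ratios at single genes best known from other tissues, such as TYRP1, KCNK3 and HEPH, picked after their values were seen; no excess of such genes was shown. For the called spots with a duplicate, the duplicates argue against a defect of single spots. For 12 called spots of 11 probes, 100% of the duplicates had the same sign, with a median of 1.85 when turned to it. Only the 2 spots of ZNF395, each the duplicate of the other, both passed. Over all duplicate pairs agreement was far from complete, with Pearson correlations of 0.346 to 0.492 on single arrays (635 to 764 pairs). For means over the arrays the correlation was 0.677 (594 pairs). Carry-over along the order of rows is not seen, with 2 neighbouring pairs of called probes against a mean of 1.33 in 10000 random placements (p = 0.387, permutation, one-sided). A larger error at silent genes predicts a wider spread between arrays. For 69 probes of olfactory and taste receptors, crystallins, keratin-associated and sperm proteins the median SD was 0.56. It was 0.28 for 162 probes of ribosomal, oxidative phosphorylation and proteasome genes, a ratio of 2.01 (permutation p = 1e-04, one-sided, the smallest that 10000 permutations give). Over all tested probes the median SD was 0.48, so the ratio rests largely on a narrow comparison group. Mean ratios of at least 2-fold were found for 4.12% of silent-family probes and 4.95% of other named probes. The share was 1.76% for the ribosomal, oxidative phosphorylation and proteasome probes. Large ratios were thus not more frequent in the silent families than in other named probes. Whether dim spots pass more often stays open, since 1 of 97 silent-family probes and 123 of 16763 other named probes passed, a ratio of shares of 1.405 (two-sided Fisher's exact p = 0.512), and even 0 of 97 would have given a one-sided Fisher's exact p of 0.491. A response of these genes to infection stays open.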

How the results depend on the processing

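Keeping the control and blank positions, and using only probes with exactly 1 symbol, were alternatives chosen after seeing the data; the others were planned. The 171 called probes (167 at 2-fold or more) became 0 (0) without variance moderation, where 2659 had an unadjusted p under 0.05 and the smallest adjusted p was 0.108, because each variance then rests on at most 5 values. They became 20 (20) at an adjusted p of 0.01 and 2808 (883) at an unadjusted p of 0.05. Without 1 replicate the count ran from 12 to 98 in both, with fewer arrays in each fit. The other alternatives gave 141 to 246 probes (135 to 236 at 2-fold or more), including 183 after centring (67.2% higher, against 63.7%), 184 with control and blank positions kept and 141 with exactly 1 symbol. At unadjusted p 43.3% were higher.

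The median correlation between arrays was 0.18 by Spearman in place of 0.278. The 3 called lists became 0 with an estimated correlation, 6 with fry, which also called the inflammatory, monocyte and aminoacyl-tRNA synthetase lists, and 1 to 3 without a replicate. The glycolysis list was called without any single replicate, with medians between −0.36 and −0.27, and the cholesterol list was lost without replicate 4. Centring and scaling kept the calls of all 24 named probes; without moderation all 24 were lost, and without a replicate 4 to 13 remained. NCF1 turned to −0.038 with array weights and ran from −0.13 to 0.064 without a replicate, MPO from −0.0042 to 0.087 and TLR2 from −0.28 to 0.090; none of them passed in any setting. The cause of these moves was not tested. No paired analysis was possible because there is a single group, and each ratio already pairs the infected and the mock culture of a replicate. Signal over background, which limits the ratios of dim spots, is unknown.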

Other observations

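Both gene lists of this part were written after the main results were known, the glycolysis and cholesterol lists and the called probes included. They were recorded as written before the values of their members were looked at. The hypoxia list is not shown to be independent of the earlier results. ZNF395 has a called probe, and DDIT4 and INSIG2 also passed over all genes in the earlier fit. NDRG1 was picked after its value was seen. Of 26 hypoxia-induced genes outside the glycolysis list 20 had negative ratios, and the median was −0.36, negative on 5 of 5 arrays. The group passed cameraPR (adjusted p = 1.05e-06 over the 2 lists) but not with an estimated correlation (adjusted p = 0.0515). Over all genes in limma 3 of them fell: DDIT4, an inhibitor of mTOR signalling (−1.59 ± 0.45, adjusted p = 0.032), INSIG2, which retains the sterol sensor in the endoplasmic reticulum (−1.69 ± 0.52, adjusted p = 0.0339), and ZNF395 (−1.25 ± 0.33, adjusted p = 0.0354). The collagen prolyl hydroxylase P4HA2 (−0.87 ± 0.32) and the MYC antagonist MXI1 (−0.78 ± 0.25) did not pass, and PDK3 (0.72 ± 0.31) and BHLHE40 (0.67 ± 0.35) had positive ratios. NDRG1, another gene that hypoxia induces, fell as well (−1.82 ± 0.30, adjusted p = 0.0115), and the mitophagy receptors BNIP3L and BNIP3 stood at −0.62 ± 0.20 and −0.86 ± 0.91.

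Genes driven by the sterol-regulated transcription factors SREBP outside the cholesterol list had a median of −0.12, with 15 of 20 negative and the median negative on 5 of 5 arrays. This group also passed cameraPR (adjusted p = 0.00549) but not with an estimated correlation (adjusted p = 0.0696). The members of smallest p were the stearoyl-CoA desaturase SCD (−0.79 ± 0.14, adjusted p = 0.0565) and the cholesterol carrier STARD4 (−0.94 ± 0.34, adjusted p = 0.0705). FADS1 stood at −0.45 ± 0.20 and GPAM at −0.43 ± 0.16, and in limma 0 of the 20 passed over all genes, with 6 lower and 0 higher at an unadjusted p under 0.05.

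If the likely direction holds, a candidate explanation of the lower glycolysis list is weaker hypoxia-responsive transcription in infected cultures relative to mock. With values deposited as mock over infected, it would be stronger instead. The hypoxia targets outside that list moved the same way as the list, with a median of −0.36 and 20 of 26 negative, within the limits of the tests given above. Inside the glycolysis list 7 of 23 members had positive ratios, the glucose transporter SLC2A1 among them. Whether a few members carry the glycolysis result was not settled: without the 5 of smallest p the other 18 had a median of −0.19, negative on 4 of 5 arrays. The density or oxygen supply of the cultures, which could differ between infected and mock cells, was not measured here. For the cholesterol list, lower sterol-responsive transcription is a candidate explanation, and its outside targets had a median of −0.12, with the same limits. Both hypotheses rest on the same 5 arrays as the patterns they address, and both take the likely direction of the ratios. With the dyes never exchanged, a dye effect shared by members of a list cannot be told apart from infection either.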
